A study of Mus musculus with 9 samples.

How the data were processed

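Hippocampus was collected from 11-day-old mice, 4 with an endothelial knockout of Slc38a3 (cKO) and 5 wild type (WT). Per the labels' protocols, total RNA was made into stranded libraries with a directional kit, all at the same time. Groups and sex came from the labels. Replicate numbers follow the order of the records and pair no samples across groups. Libraries of one group differed by 4.04 to 15.4 in chi-square per gene, above sampling noise in every pair, so no pair was treated as 1 library. That check does not show that the libraries are independent.

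Per the submitters' processing notes, FastQC 0.12.1, cutadapt 4.4, STAR 2.7.10b and DESeq2 1.41.8 were used with the GRCm39 build. The read counter, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited file is 1 table of 57180 genes with a signal value per gene and library, which the values show to be gene counts divided by 1 size factor per library and rounded to 2 decimals. Normalized counts by the authors compare libraries but not genes of different length. Dividing by the step of each library, 0.943 to 1.08, gave whole reads within 0.1 read for 100.0% of the values above 0, and totals of 30803135 to 34034530 reads per library. In cKO replicate 1, WT replicate 1 and WT replicate 4 the step lies so close to 1 that the rounding alone hardly differs from it at low values. The range of depth was narrow, and low genes carry the larger counting error. Coordinates are those of the deposited table. No column of values was left out. Results of single genes that are withheld are not reported here, and the counts and tests over all genes and lists include them.

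The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), with sex and genotype as terms, over the 17036 genes with a mean of at least 10 in all 9 libraries, and Benjamini-Hochberg adjusted p under 0.05. A fold change is on that scale, which understates the change of low genes, and comes from the model with sex as a term, so it can differ from the ratio of the group means. The same fit gave the difference between the sexes, and a further fit the interaction of sex and genotype. Slc38a3 also had an exact permutation test over all splits. camera (preset correlation 0.01) tested 37 gene lists, and 2 lists of sex-linked genes were described only. The lists held 837 entries, of which 3 were not matched to a gene and 6 were matched by an older symbol. With sex as a term, the only cKO female and the only WT male weigh heavily in the genotype estimate.

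Before the data were examined, the samples, tests, lists, alternatives and the rule for naming genes were fixed. The rule named Slc38a3, the 12 genes with the largest rise and the 12 with the largest fall among those passing with a mean of at least 50 (leaving out sex-linked genes and symbols that are identifiers), up to 4 members of smallest p per list, up to 4 genes per direction for sex, and up to 4 passing genes for the interaction. C4a was named after its values were seen, as a copy of C4b. Of the passing genes, 17 higher and 35 lower met the rule and 7 were left out by it.

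The scripts were tested on simulated counts drawn from the real genes' means, with 200 genes changed. For cKO against WT over 17036 genes, limma-trend called 37.3% of genes changed 1.25-fold, 79.1% of those changed 1.5-fold and 93.9% of those changed 2-fold, with 8 false among 148 calls. A simulated list of 25 genes shifted by 0.2 on the log2 scale had a camera p of 2.49e-25, and 3.5% of 200 unchanged lists had a p under 0.05. The simulated genes were drawn independently of each other. That share therefore does not hold for real lists whose genes vary together, such as the ribosomal list with an estimated correlation of 0.662. Nor does the number of false calls hold where samples share a structure. In the real data a split that mixed the genotypes, cKO replicates 1 and 4 with WT replicates 2 and 4, gave 49 genes. The alternatives were other pseudocounts (0.5 and 5), other filters, TMM scaling, robust limma, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, no sex term, each sex alone, covariates from marker lists, and each library left out in turn. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures. Since the labels do not say from which litters the animals came, p-values measure the spread between these samples.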

Results

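RNA-seq was performed on whole hippocampus of 11-day-old mice on a C57BL6 background. 4 animals (cKO) lacked Slc38a3, which encodes the sodium-coupled glutamine transporter SNAT3, in endothelial cells, and 5 were wild type (WT). Each library came from a separately labelled sample. The cKO group held 3 males and 1 female, and the WT group 1 male and 4 females, so sex was unevenly split between the genotypes and entered the main models as a term. The deposited values are gene counts divided by a size factor per library (normalized counts). The reads recovered from them numbered 32096409 to 34034530 per cKO library and 30803135 to 33134405 per WT library. Of 57180 genes in the table, 17036 had a mean of at least 10 normalized counts and were tested.

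The targeted gene was examined first, since the knockout is restricted to 1 cell type and the RNA came from whole tissue. Slc38a3 (ENSMUSG00000010064, chromosome 9, 107527832 to 107546729 in GRCm39) fell 7.97-fold, from 2821 ± 829.8 normalized counts in WT (SD, n = 5) to 351 ± 49.4 in cKO (SD, n = 4). The log2 fold change was -2.99 ± 0.221 (SE, limma adjusted p = 5.54e-05). The cKO replicates 1 to 4 held 379.8, 405, 308 and 310.2 normalized counts, below all 5 WT libraries. In an exact permutation test over every split of the 9 libraries into 4 and 5, the real split gave the largest difference without a sex term (two-sided p = 0.00794, the smallest this design allows). The WT libraries themselves were spread: WT replicates 1, 3 and 4 held 3392, 3514 and 3363 normalized counts, and WT replicates 2 and 5 held 2033 and 1804. Which exons the deletion removes is not given in the sources used here, and the values count whole genes.

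**Figure D1:**
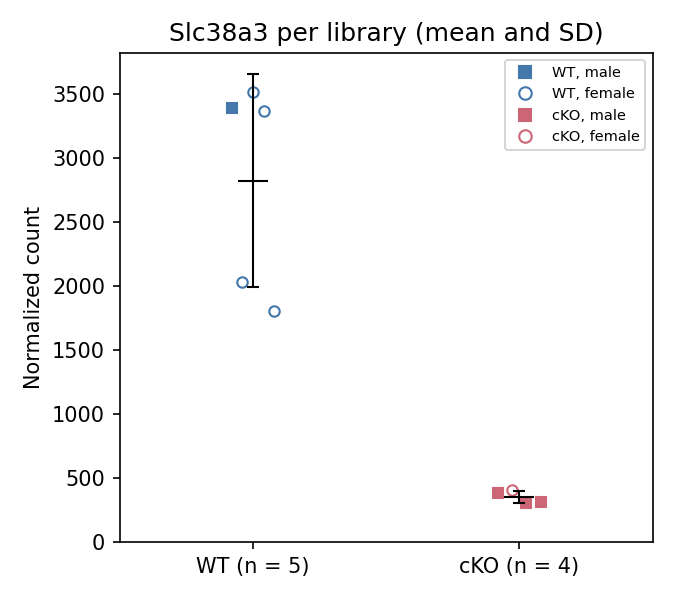
Normalized count of Slc38a3 (vertical axis, from 0) in each WT and cKO library, with squares for males and open circles for females, and bars for the mean and SD of each group. The 4 cKO libraries sit between 308 and 405, and the 5 WT libraries between 1804 and 3514.

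The main comparison asked which genes differ in the hippocampus between cKO and WT animals. Genes of astrocytes, of cholesterol synthesis and of vessels were among those that fell, and the complement gene C4b and the astrocyte genes Gfap and S100b were among those that rose. The largest rise by fold among the genes that met the naming rule was that of C4b (ENSMUSG00000073418, chromosome 17, 34947353 to 34962856), which encodes complement component 4 and has a near-identical neighbouring copy, C4a, that can share its reads. C4b rose 2.35-fold, at 548 ± 67.4 normalized counts in cKO (SD, n = 4) and 239.6 ± 29.7 in WT (SD, n = 5) (adjusted p = 0.000402), while C4a was at 68.8 ± 10.5 in cKO and 54.9 ± 12.7 in WT. Grin2c (ENSMUSG00000020734, chromosome 11, 115139994 to 115158069), an NMDA receptor subunit, fell 1.78-fold, at 483 ± 44.9 normalized counts in cKO (SD, n = 4) and 891 ± 76.6 in WT (SD, n = 5) (adjusted p = 0.00104). Tnc (ENSMUSG00000028364, chromosome 4, 63878021 to 63965252), which encodes the matrix protein tenascin C, fell 1.51-fold, at 2109 ± 156 normalized counts in cKO (SD, n = 4) and 2965 ± 246 in WT (SD, n = 5) (adjusted p = 0.000153).

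In all, 59 of 17036 genes passed, 21 higher and 38 lower in cKO (limma-trend, Benjamini-Hochberg adjusted p under 0.05), and 1932 had an unadjusted p under 0.05. Fold changes ran from 1.16 to 7.97, with 55 of the 59 genes under 2-fold. In 51 of the 59 genes the cKO and WT libraries did not overlap. Over all genes tested, 6.29% did not overlap, where chance gives 1.59%. Among the genes that met the naming rule, those that rose by the largest factor beside C4b were Lsp1 (1.80-fold), Txnip (1.61-fold), the growth factor gene Mdk (1.52-fold), Ap1g2 (1.47-fold), Fam107a (1.40-fold), Pnpla7 (1.37-fold), the transcription factor gene Atf5 (1.31-fold), Phgdh (1.30-fold), S100b (1.27-fold), Fmo1 (1.27-fold) and Ndrg2 (1.252-fold). Under the same rule, those that fell most beside Slc38a3, Grin2c and Tnc were the desaturase gene Scd1 (1.60-fold), the BMP antagonist gene Chrdl1 (1.49-fold), the opioid precursor gene Pdyn (1.47-fold), the glial potassium channel gene Kcnj10 (1.45-fold), Dio2, whose product converts thyroxine to its active form (1.38-fold), Apln (1.37-fold), the sterol transfer gene Stard4 (1.35-fold), the caveolin gene Cav1 (1.33-fold) and Daam2 (1.31-fold).

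The count depended on the samples and the model. It was 216 without the sex term, 11 in females only, 3 in males only, 199 with DESeq2 on the recovered reads, 15 without WT replicates 2 and 5, and 13 with the mean of the meningeal genes as a covariate. Leaving out 1 library gave 10 genes without cKO replicate 2, the only cKO female, 21 without WT replicate 1, the only WT male, 28 without cKO replicate 1, 29 without WT replicate 2 and 30 without WT replicate 5. With the meningeal covariate all 21 genes that rose and all 38 that fell kept their direction, each group with a median of 98.7% of its change. The median SE grew from 0.0673 to 0.0762 and from 0.0545 to 0.0646. C4b, Tnc, Kcnj10 and Slc38a3 passed with each of the 9 libraries left out in turn. Each of the other 55 genes lost its call without cKO replicate 2, WT replicate 1 or both. With sex as a term, those 2 fits set the genotype effect within 1 sex, against a single WT male or cKO female. Slc38a3 was then at -3.353 and -2.659, as in males only and females only. The 59 genes kept a median of 96.44% and 103.3% of their change, while their median SE of 0.05584 grew to 0.07898 and 0.07566. A call lost there does not show that it depended on the animal left out.

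**Figure D2:**
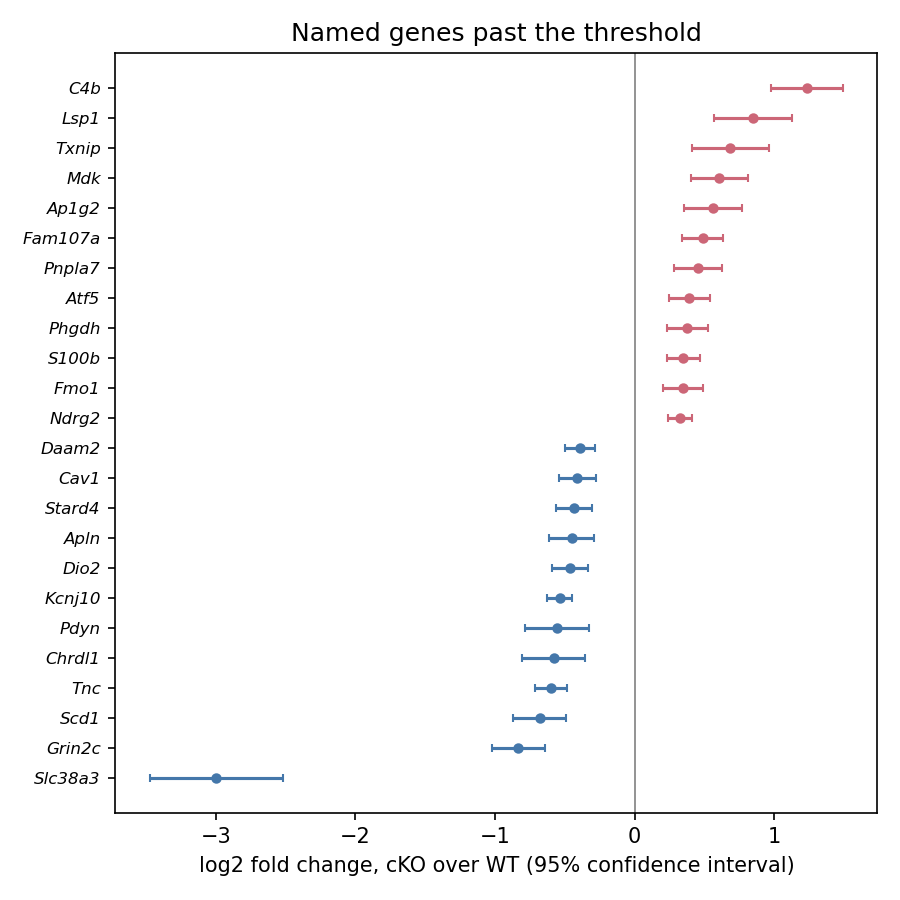
Log2 fold change of cKO over WT (horizontal axis) for the 12 genes that rose and the 12 that fell by the largest amounts among those that met the naming rule, with 95% confidence intervals from limma. Slc38a3 lies at -2.99 and the others shown between -0.83 (Grin2c) and 1.23 (C4b).

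Cholesterol synthesis genes were lower in cKO as a group. Of 22 members tested, 8 fell, none rose and 14 did not pass, and all 22 had a fold change below 0. Adjusted over the list alone, 18 were lower and 0 higher. Hmgcs1, an early enzyme of the pathway, fell 1.24-fold, at 19937 ± 825 normalized counts in cKO (SD, n = 4) and 25166 ± 349 in WT (SD, n = 5) (adjusted p = 0.00374). Nsdhl fell 1.29-fold (adjusted p = 0.00410) and Stard4 1.35-fold (adjusted p = 0.00642). The median log2 fold change over the list was -0.25 (camera adjusted p = 3.45e-28), and the call did not hold with an estimated correlation (p = 0.00162, adjusted p = 0.0601). With the mean of the meningeal genes, which were higher in cKO, as a covariate, the log2 fold change of Hmgcs1 was -0.28 ± 0.0465 (-0.31 ± 0.0406 without it, adjusted p = 0.0563 with it). That of Nsdhl was -0.36 ± 0.0580 (-0.36 ± 0.0477 without it, adjusted p = 0.0516 with it). That of Stard4 was -0.37 ± 0.0642 (-0.43 ± 0.0598 without it, adjusted p = 0.0796 with it).

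**Figure D3:**
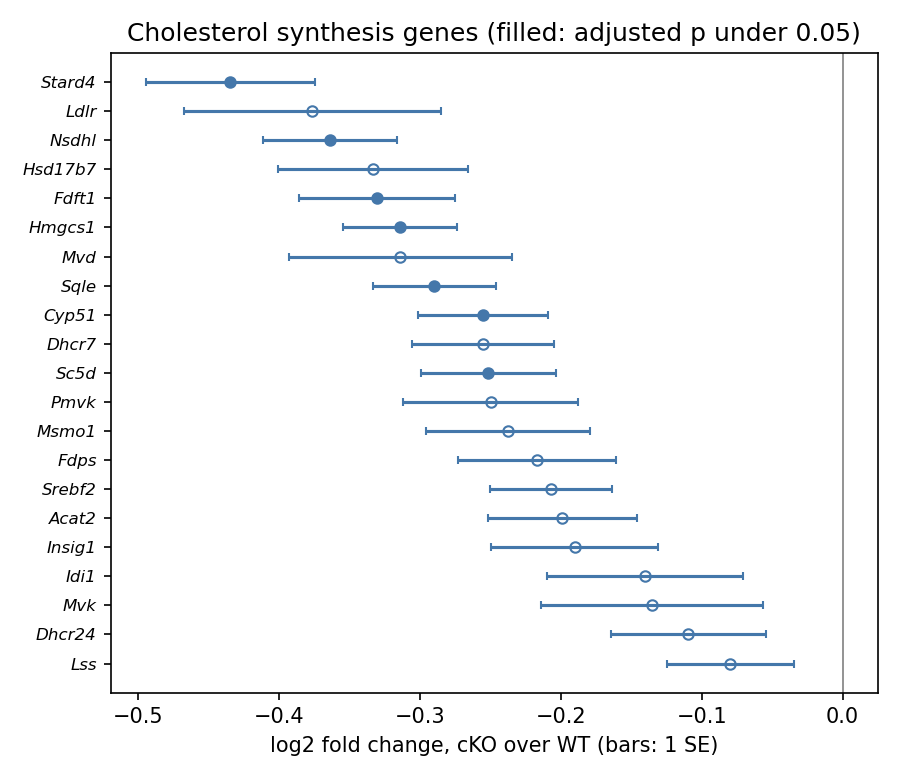
Log2 fold change of cKO over WT (horizontal axis) for the cholesterol synthesis genes reported here, with bars of 1 SE and filled points for an adjusted p under 0.05. All points lie below 0, from -0.43 (Stard4) to -0.08 (Lss).

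Astrocyte markers moved in both directions. Of 22 tested, 3 fell, 2 rose and 17 did not pass, and adjusted over the list alone 5 were higher and 4 lower. Kcnj10 (ENSMUSG00000044708, chromosome 1, 172168776 to 172201652) fell 1.45-fold, at 3787 ± 36.9 normalized counts in cKO (SD, n = 4) and 5605 ± 233 in WT (SD, n = 5) (adjusted p = 5.54e-05). The water channel gene Aqp4 fell 1.27-fold, at 8347 ± 334 in cKO and 11001 ± 427 in WT (adjusted p = 0.00206), and Glul, which encodes glutamine synthetase, fell 1.23-fold, at 21976 ± 1779 in cKO and 28464 ± 1574 in WT (adjusted p = 0.0338). S100b rose 1.27-fold, at 1263 ± 129 in cKO and 1083 ± 73.9 in WT (adjusted p = 0.0141), and the intermediate filament gene Gfap rose 1.22-fold, at 12099 ± 1066 in cKO and 10519 ± 690.0 in WT (adjusted p = 0.0420). The list as a whole was not called (median 0.05, camera adjusted p = 0.535). Of 17 reactive astrocyte genes, 2 rose (C4b and Gfap) and 15 did not pass, with 4 higher and 0 lower adjusted over the list alone, and camera called the list higher (median log2 fold change 0.18, camera adjusted p = 0.000225, adjusted p = 0.180 with an estimated correlation). With the mean of the meningeal genes as a covariate Kcnj10, Aqp4 and C4b still passed. The log2 fold change of Glul was then -0.29 ± 0.0633 (-0.29 ± 0.0520 without it, adjusted p = 0.225 with it). That of S100b was 0.33 ± 0.0648 (0.35 ± 0.0541 without it, adjusted p = 0.130 with it). That of Gfap was 0.29 ± 0.0675 (0.29 ± 0.0553 without it, adjusted p = 0.258 with it).

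**Figure D4:**
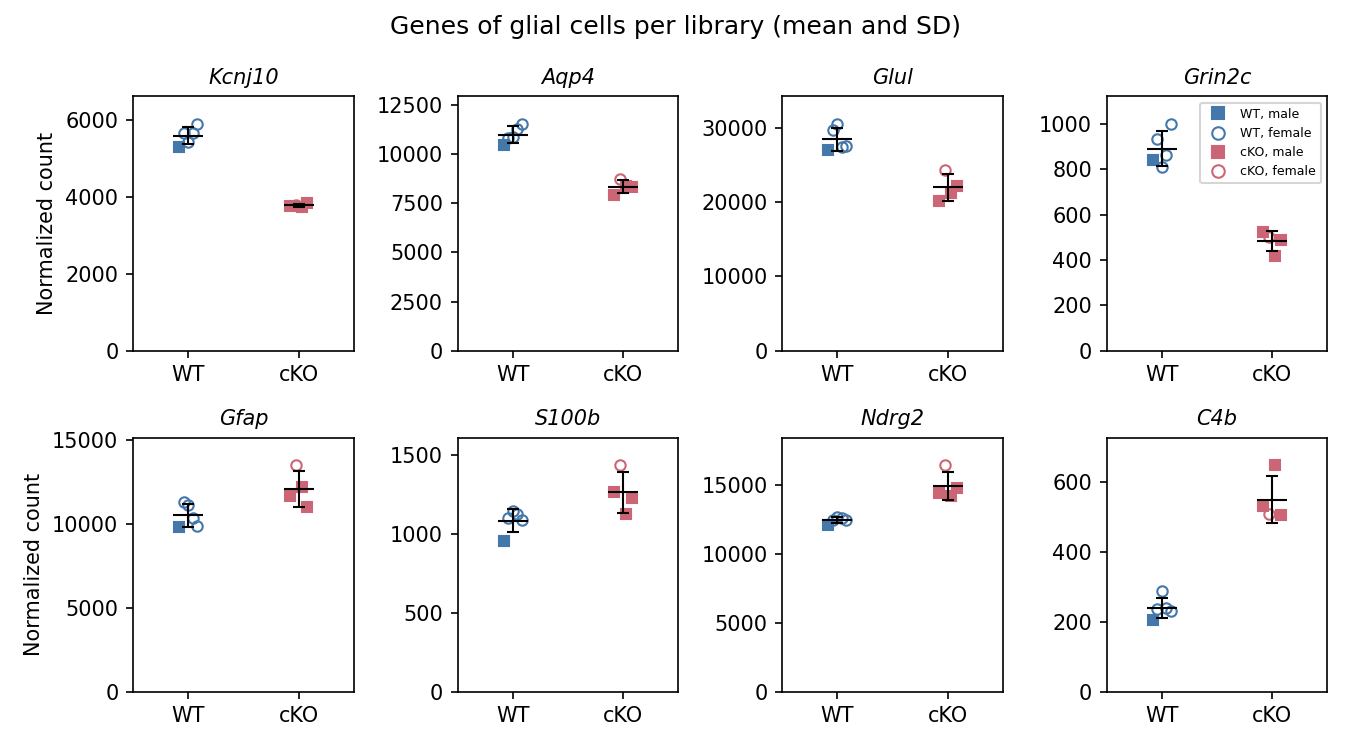
Normalized counts (vertical axes, from 0) of Kcnj10, Aqp4, Glul and Grin2c, which fell, and of Gfap, S100b, Ndrg2 and C4b, which rose, in each WT and cKO library, with squares for males, open circles for females and bars for the mean and SD. For Kcnj10 the cKO mean was 3787 and the WT mean 5605, and for Gfap they were 12099 and 10519.

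Among vessel genes, those that passed all fell. Of 27 endothelial cell markers, 1 fell, 0 rose and 26 did not pass, with 5 lower and 0 higher adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 0.000405, adjusted p = 0.476 with an estimated correlation). The marker that fell was Flt1, a VEGF receptor gene, at 1233 ± 86.3 in cKO and 1546 ± 75.9 in WT normalized counts (1.27-fold, adjusted p = 0.0417). Of 30 blood-brain barrier genes, 3 fell and 27 did not pass, with 6 lower and 0 higher adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 6.28e-05, adjusted p = 0.111 with an estimated correlation). These 3 were Slc38a3 itself, Cav1 (1.33-fold, 762 ± 44.4 in cKO and 1018 ± 39.3 in WT, adjusted p = 0.0125) and the thyroxine transporter gene Slco1c1 (1.20-fold, 3038 ± 61.5 in cKO and 3719 ± 89.5 in WT, adjusted p = 0.00974). Without Slc38a3, the deleted gene, 2 of the 29 others fell, with 3 lower and 0 higher adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.000568, adjusted p = 0.167 with an estimated correlation). Of 25 genes of vessel growth and its Wnt and Notch signals, Vegfa, Apln and Flt1 fell and 22 did not pass, with 1 higher and 4 lower adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.00348, adjusted p = 0.180 with an estimated correlation). Vegfa, the main vessel growth factor gene, was at 1801 ± 71.7 in cKO and 2208 ± 80.8 in WT (1.24-fold, adjusted p = 0.0220). It was also the 1 member that fell of 25 hypoxia and glycolysis genes, of which 2 higher and 4 lower passed adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 8.64e-05, adjusted p = 0.241 with an estimated correlation). Mural cell markers were not called, with a median of -0.10 (adjusted p = 0.357), a mean of 0.06 and 0 higher and 3 lower adjusted over the list alone. With the mean of the meningeal genes as a covariate Vegfa still passed. The log2 fold change of Flt1 was then -0.40 ± 0.0721 (-0.34 ± 0.0640 without it, adjusted p = 0.0843 with it). That of Cav1 was -0.37 ± 0.0724 (-0.41 ± 0.0627 without it, adjusted p = 0.127 with it). That of Slco1c1 was -0.27 ± 0.0476 (-0.27 ± 0.0390 without it, adjusted p = 0.0813 with it). That of Apln was -0.49 ± 0.0883 (-0.45 ± 0.0753 without it, adjusted p = 0.0813 with it). The call of the endothelial list was lost without WT replicate 1 (median -0.03, adjusted p = 0.13), as was that of the vessel growth list (median -0.05, adjusted p = 0.084). Calls that held moved too, with a median of -0.13 for the barrier list without WT replicate 1, and without cKO replicate 2 of -0.17 for the endothelial and -0.12 for the vessel growth list.

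Genes of the amino acid response were higher in cKO. Of 32 ATF4 targets, 2 rose and 30 did not pass, with 5 higher and 0 lower adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 9.25e-06, adjusted p = 0.167 with an estimated correlation). Atf5 was at 944 ± 62.1 in cKO and 702 ± 37.7 in WT (1.31-fold, adjusted p = 0.0323), and Phgdh, the first enzyme of serine synthesis, at 1666 ± 184 in cKO and 1333 ± 38.5 in WT (1.30-fold, adjusted p = 0.0353). The log2 fold change of Phgdh was 0.38 ± 0.0673 with all libraries and 0.19 ± 0.0658 without cKO replicate 2, adjusted p = 0.512. With the mean of the meningeal genes as a covariate that of Atf5 was 0.41 ± 0.0816 (0.39 ± 0.0679 without it, adjusted p = 0.130 with it). That of Phgdh was 0.43 ± 0.0762 (0.38 ± 0.0673 without it, adjusted p = 0.0813 with it). No other member of the Slc38 family passed besides Slc38a3 among 10 tested (median 0.02, mean -0.30, camera adjusted p = 0.381). Without Slc38a3 the mean was 0.0028 (adjusted p = 0.822). The log2 fold change was -0.30 ± 0.110 for Slc38a5 (adjusted p = 0.330) and 0.13 ± 0.0542 for Slc38a2 (adjusted p = 0.371). That of Slc38a2 was 0.03 ± 0.0649 without WT replicate 1, adjusted p = 0.859, and 0.24 ± 0.0670 without cKO replicate 2, adjusted p = 0.316. Of 29 other amino acid transporters, 2 fell, Slc7a2 (1.29-fold, adjusted p = 0.0125) and Slc36a1 (1.19-fold, adjusted p = 0.0420), with 2 higher and 5 lower adjusted over the list alone, a median of -0.0027 (adjusted p = 0.684) and a mean of 0.02. The log2 fold change of Slc36a1 was -0.25 ± 0.0468 with all libraries and -0.16 ± 0.0590 without cKO replicate 2, adjusted p = 0.536. Of 21 enzymes of glutamine, glutamate and GABA, 1 fell, Glul, over all genes and over the list alone, and the median was -0.04 (adjusted p = 0.250). Of 32 glutamate signalling genes, 1 fell, Grin2c, and 31 did not pass, with 0 higher and 2 lower adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 1.60e-05, adjusted p = 0.180 with an estimated correlation), a call lost without cKO replicate 2 (median -0.04, adjusted p = 0.078), with a median of -0.13 without WT replicate 1. Of 25 GABA signalling genes 0 passed, with 0 higher and 0 lower adjusted over the list alone (median log2 fold change -0.07, camera adjusted p = 0.0359, adjusted p = 0.476 with an estimated correlation), and that call was lost without cKO replicate 2 (median -0.02, adjusted p = 0.94), WT replicate 4 (median -0.05, adjusted p = 0.092) or WT replicate 5 (median -0.05, adjusted p = 0.055).

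Markers of other cell types were examined beside these groups. Meningeal and fibroblast genes were higher in cKO (median log2 fold change 0.39, camera adjusted p = 0.000117, adjusted p = 0.476 with an estimated correlation), although 0 of 20 members passed over all genes and 3 higher and 1 lower passed adjusted over the list alone. The mean log2 value of this list was 8.35 ± 0.298 in cKO (SD, n = 4) and 7.98 ± 0.333 in WT (SD, n = 5), so the groups differed by about the spread between libraries. Col1a1 was at 1901 ± 181 in cKO and 1425 ± 260.5 in WT (adjusted p = 0.129). Of the 20 members, 3 are in another list too. Microglia markers were lower (median log2 fold change -0.09, camera adjusted p = 0.0147, adjusted p = 0.463 with an estimated correlation), with 1 higher and 3 lower of 21 adjusted over the list alone and P2ry12 at 977 ± 117 in cKO and 1288 ± 56.8 in WT (adjusted p = 0.0844). Oligodendrocyte precursor markers were lower (median log2 fold change -0.09, camera adjusted p = 9.18e-05, adjusted p = 0.153 with an estimated correlation), with 14 of 14 fold changes below 0 and 0 higher and 3 lower adjusted over the list alone. Myelin genes were higher with the sex term (median log2 fold change 0.11, camera adjusted p = 0.00377, adjusted p = 0.617 with an estimated correlation), with 0 higher and 0 lower of 25 adjusted over the list alone, although the mean log2 value of the list was 8.81 ± 0.299 in cKO and 8.92 ± 0.201 in WT. Blood cell genes were lower (median log2 fold change -0.15, camera adjusted p = 0.0354, adjusted p = 0.476 with an estimated correlation), with 0 of 7 members passing either way. Without WT replicate 1 the call of the meningeal list was lost and its test turned (median 0.07, adjusted p = 0.78), and those of the microglia (median 0.01, adjusted p = 0.83), precursor (median -0.04, adjusted p = 0.13) and myelin lists (median 0.09, adjusted p = 0.084) were lost. That of the blood list was lost without cKO replicate 3 (median -0.12, adjusted p = 0.099) or WT replicate 4 (median -0.14, adjusted p = 0.068) and turned without cKO replicate 2 (median 0.07, adjusted p = 0.78), and the myelin list turned without the sex term (median -0.08, adjusted p = 0.1). Where the calls held, the median also moved without cKO replicate 2 in the meningeal (0.75), microglia (-0.17), precursor (-0.18) and myelin lists (0.17). It moved in the myelin list without cKO replicate 1 (0.16) or 4 (0.05), and in the blood list without WT replicate 1 (-0.46).

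No member passed over all genes, and camera made no call, in the lists of the regions and remaining cell types. The median was 0.19 (adjusted p = 0.377) for choroid plexus markers, 0.0017 (adjusted p = 0.823) for ependymal genes, -0.02 (adjusted p = 0.913) for interneuron genes and -0.04 (adjusted p = 0.445) for immature neuron genes. It was 0.03 (adjusted p = 0.335) for granule cells of the dentate gyrus, -0.07 (adjusted p = 0.250) for CA1 and -0.03 (adjusted p = 0.823) for CA2 and CA3 pyramidal cells, whose mean lay just above 0. For the tissues next to the hippocampus it was 0.03 (adjusted p = 0.679) for thalamus, 0.04 (adjusted p = 0.357) for neocortex and 0.17 (adjusted p = 0.118) for striatum. Adjusted over the list alone, 1 higher and 0 lower passed among granule cell genes and 0 higher and 1 lower among CA2 and CA3 genes. Among immature neuron genes 3 higher and 3 lower passed, and 0 in the other lists of this group. Choroid plexus genes varied widely between libraries. Their mean log2 value ran from 5.147 (cKO replicate 3) to 8.738 (WT replicate 2), at 6.99 ± 1.55 in cKO and 7.12 ± 1.43 in WT. That of the striatum list ran from 7.569 (WT replicate 2) to 8.750 (cKO replicate 4). With the choroid plexus mean as a covariate 48 genes passed, 45 of the 59 among them.

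Several lists of housekeeping and activity genes were called although no member passed over all genes. Of 34 cytosolic ribosomal protein genes, 33 had a fold change above 0 (median log2 fold change 0.09, camera adjusted p = 8.25e-10, adjusted p = 0.463 with an estimated correlation), and of 30 cell cycle genes 28 had one below 0 (median log2 fold change -0.18, camera adjusted p = 2.21e-06, adjusted p = 0.241 with an estimated correlation). Immediate early genes were lower, in 22 of 24 members (median log2 fold change -0.12, camera adjusted p = 0.000912, adjusted p = 0.476 with an estimated correlation), with Arc at 1005 ± 251 in cKO and 1413 ± 97.7 in WT (adjusted p = 0.308). Endoplasmic reticulum stress genes were lower in 16 of 20 members (median log2 fold change -0.08, camera adjusted p = 0.000507, adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, 0 ribosomal and 0 cell cycle genes passed, 0 higher and 1 lower among immediate early genes and 0 higher and 1 lower among stress genes. The ribosomal call was lost without cKO replicate 2 (median 0.02, adjusted p = 0.44), and the immediate early genes turned without WT replicate 1 (median 0.05, adjusted p = 0.72). Where the calls held, the ribosomal median was 0.18 without WT replicate 1, and that of the immediate early genes -0.28 without cKO replicate 2 and -0.07 without cKO replicate 3. Not called were glucocorticoid response genes, with a median of 0.01 (adjusted p = 0.250) and 2 higher and 0 lower adjusted over the list alone, and 3 lists with 0 members passing either way. For interferon response genes the median was -0.08 (adjusted p = 0.835), for nuclear genes of the respiratory chain 0.01 (adjusted p = 0.872), and for mitochondrially encoded genes -0.00076 (adjusted p = 0.516), whose mean was 0.04.

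Over the 37 lists, camera with a preset correlation of 0.01 called 18, 5 higher and 13 lower. Among 100 splits of the 9 libraries, the real one included, 6 gave as many lists, and the highest other gave 21. Chance can thus not be excluded for the number of lists. With an estimated correlation camera called 0, with 8 lists at an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move one way on balance, called 4, 1 higher and 3 lower. The ATF4 targets were higher (fry adjusted p = 0.0453). Lower were the cholesterol synthesis (fry adjusted p = 0.00274), blood-brain barrier (0.0205) and endoplasmic reticulum stress genes (0.0339). Without Slc38a3 the barrier list had a fry adjusted p of 0.0453.

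The sex term was used to check the sex labels. Xist, transcribed from the inactive X chromosome, was higher in females with a log2 difference of 11.11 ± 0.499 (adjusted p = 9.18e-08), and the Y-linked genes Eif2s3y, with -8.00 ± 0.461 (adjusted p = 1.18e-06), Kdm5d, with -7.58 ± 0.546 (adjusted p = 1.35e-05), and Uty, with -7.97 ± 0.623 (adjusted p = 2.26e-05), were lower. Xist was at 16142 normalized counts or more in each library labelled female and at 37.7 or less in each labelled male. In all, 9 genes passed, 3 higher and 6 lower in females, and 1146 had an unadjusted p under 0.05. Eif2s3x, the X-linked partner of Eif2s3y, was higher, with 0.57 ± 0.0614 (adjusted p = 0.000662). Tbc1d1, on chromosome 5, was higher, at 1269 ± 44.6 normalized counts in females (SD, n = 5) and 797 ± 37.4 in males (SD, n = 4), a log2 difference of 0.68 ± 0.0575 (adjusted p = 4.27e-05). DESeq2 on the recovered reads called 24 genes, and 16 passed without cKO replicate 4. In the list of Y-linked genes and Xist, 0 of 6 passed between genotypes (median 0.88), and in that of X-linked genes with a Y copy or escaping inactivation 0 of 8 (median -0.02).

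Whether the genotype difference was unequal in males and females was tested with an interaction term, for which the cKO females and the WT males numbered 1 each. 1 gene of 17036 passed, Sorcs2 (ENSMUSG00000029093, chromosome 5, 36174523 to 36555483), which encodes a sorting receptor of neurons. Its libraries held 1520.4, 1465 and 1449 normalized counts in the cKO males and 2696 in the cKO female, and 2964 in the WT male and 2715 to 2959 in the WT females. The interaction was 0.92 ± 0.0908 on the log2 scale (adjusted p = 0.00341). At an unadjusted p under 0.05 the term was met by 1346 genes. DESeq2 called 7 genes and edgeR 1. Without a filter on low genes limma called 919, of which 875 had a mean under 10 normalized counts.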

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

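Except for the counts over other splits of the samples, the tests of explanations in this part were chosen after the results were seen. A value was singled out when its gap to the nearest of its group exceeded the range expected for 95% of groups (Dixon's ratio), within sexes for genes that follow sex. Of 369 groups, 25 met this, where chance gives 18.4.

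Set apart in normalized counts were Cldn11 in WT replicate 1 (657.2, others 979.4 to 1003), Fa2h in WT replicate 1 (163.6, others 224.3 to 248), Mag in WT replicate 1 (803.8, others 1201 to 1323) and Dpysl3 in WT replicate 1 (44700, others 37620 to 39010). Further such values were those of Chrdl1 in WT replicate 2 (309.5, others 352 to 367.5), Dkk3 in WT replicate 2 (7891, others 7264 to 7365), Txnip in WT replicate 3 (1437, others 913.5 to 1004) and Scd1 in WT replicate 3 (5824, others 4705 to 4883). The gap was also large for Slc6a13 in WT replicate 3 (305.1, others 166.7 to 201.4), Hydin in WT replicate 3 (192.7, others 118.3 to 139.6), Zic1 in WT replicate 3 (1492, others 563.3 to 753.8) and Gpt in WT replicate 4 (195.8, others 235.8 to 247.3). Also apart were Daam2 in WT replicate 5 (2960, others 2696 to 2769), Slc7a2 in WT replicate 5 (1373, others 1198 to 1225), Phgdh in cKO replicate 2 (1939, others 1539 to 1593) and the gene without a symbol ENSMUSG00000095041 in cKO replicate 2 (10080, others 7207 to 7995). Others in this set were Sorcs2 in cKO replicate 2 (2696, others 1449 to 1520), Socs2 in cKO replicate 2 (1609, others 1377 to 1411), Hyou1 in cKO replicate 2 (3499, others 3698 to 3732) and Hba-a1 in cKO replicate 3 (390.9, others 505.3 to 510.1). The remaining genes were Pcp4 in cKO replicate 3 (718.9, others 805.4 to 820.6), Sult1a1 in cKO replicate 3 (65.79, others 106.6 to 113.4) and Trhr in cKO replicate 4 (518.6, others 311.4 to 345). For list means on the log2 scale, WT replicate 1 lay apart at 8.562 for myelin genes (others 8.947 to 9.035) and at 11.36 for cholesterol synthesis genes (others 11.28 to 11.3). Sorcs2 passed the interaction test of sex and genotype, at 0.9249 on the log2 scale. With 1 cKO female and 1 WT male, an unequal effect by sex was not separated from 1 unusual animal, and of the cKO libraries cKO replicate 2 alone lay near the WT libraries.

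Slc38a3 differed between the WT libraries, from 1804 to 3514 normalized counts, a range of 0.961 on the log2 scale against 0.1844 for the mean of the endothelial list, which argues against an unequal share of endothelial cells. RNA of cKO animals mixed into WT replicates 2 and 5 had been left open by a first test over 50 genes. Its smallest excess over the position of Slc38a3, 0.210 and 0.204, lay within its last bound of 0.405. That bound had been changed in turn, and an earlier one of 0.202 lay below both values. The test was then replaced after its values were seen. The tests that replaced it argue against mixing as the whole cause. The Y-linked genes stood at no more than 0.3503% of the cKO males there, where Slc38a3 would need a share of cKO RNA of 46.8% and 54.0%. This covers RNA of cKO males only, since the cKO female itself stood at 0.604%. Of the genes that passed with only that library left out, at least 89.29% lay nearer to WT than Slc38a3 did, whether set against all cKO libraries or the cKO female. The next values are set against the mean of all cKO libraries only. From that mean (0) to the other WT libraries (1), over the fits without the library alone or with 1 other WT library, the genes that passed lay above Slc38a3 in 71.4% of cases at the lowest (5 of 7 genes, without WT replicates 1 and 2). Their median was 0.874 to 0.928 in WT replicate 2 (Slc38a3 0.547 to 0.672) and 0.986 to 1.079 in WT replicate 5 (Slc38a3 0.473 to 0.564). The ratio of the lowest to the highest WT library, 0.5135, is what 1 recombined copy of Slc38a3 could give, and with no genotypes of these animals this cannot be told apart. No other biological explanation was tested. WT replicates 2, 3, 4 and 5 are all females of the same age, so neither sex nor age parts 2 and 5 from 3 and 4.

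Flt1, Cav1 and Slco1c1 fell in cKO. The median over the 27 endothelial markers was -0.0985 on the log2 scale, against a median of -0.343 for these 3 genes and an SD over the markers of 0.116. The 3 genes were picked because they passed, which alone would set their median beyond that of the list. Of the 27 markers, 21 had a fold change below 0. The comparison therefore cannot decide whether a lower share of endothelial cells is the whole cause. With the endothelial mean as a covariate the change of Flt1 was -0.276 ± 0.0687 (adjusted p = 0.113), that of Cav1 -0.416 ± 0.0754 and that of Slco1c1 -0.290 ± 0.0448, the last 2 past the threshold, and Flt1 is itself in that mean. An effect of the genotype on endothelial expression and a lower share of endothelial cells both stay open.

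Astrocyte genes fell and rose together in cKO. A changed share of astrocytes alone would move the markers one way, and 2 rose while 3 fell. Those directions had been seen before the test was set, so it restates them and excludes no changed share. The 2 rises depended on the libraries. S100b was at 1127 in cKO replicate 3 and 1144 in WT replicate 3, and Gfap at 11009 in cKO replicate 4 and 11340 in WT replicate 2. The sex term of the model was 0.236 for S100b and 0.165 for Gfap, higher in females, and neither passed for sex. With 1 library left out, S100b passed in 7 of 9 fits and Gfap in 1, with log2 fold changes of at least 0.3299 and 0.2371. Meninges carried along are argued against: with the meningeal mean as a covariate the 5 markers that passed kept 99.04% of their change at the median. The calls of Gfap (0.291 ± 0.0553 before, 0.294 ± 0.0675 after), S100b (0.348 ± 0.0541 and 0.328 ± 0.0648) and Glul (-0.294 ± 0.0520 and -0.291 ± 0.0633) ended with a larger SE, in a fit in which 1423 genes had an unadjusted p under 0.05, against 1932 before. A change of state of astrocytes with the genotype is a hypothesis that these data leave open, as is a litter effect, which could not be tested.

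Other splits of the 9 libraries were fitted in the same way, 100 for each result. For genotype, 1 of 100 splits, the real one, gave as many as 59 genes, and the highest other gave 49. The real split ranked first, which met the rule fixed beforehand. A split that mixes the genotypes came near it, so the count alone excludes neither chance nor another structure of the samples. For the 18 gene lists, 6 of 100 splits gave as many, with 21 in the highest other, so chance cannot be excluded for the number of lists. For sex, 4 of 100 splits gave as many as 9 genes, the real one among them, which met the rule fixed beforehand. The 3 others exceeded the real count, so the count alone does not exclude chance. The 3 other splits gave 49, 73 and 190 genes, the last with WT replicates 1, 2 and 3 and cKO replicate 2 against the rest. Counts that high point to a structure of the samples beside sex and genotype, for which no test was made. That split parts WT replicates 4 and 5 from the other WT libraries, as does the share of counts from mitochondrial genes, 3.35% and 3.31% against 2.75 to 2.94%, and that of the 10 highest genes, 4.01% and 3.99% against 3.49 to 3.65%. The cKO libraries, which it also parts, held 3.06% (replicate 2) and 2.90 to 3.06% of mitochondrial counts. The mean log2 value of the striatum list was likewise higher in WT replicates 4 and 5, at 8.589 and 8.743 against 7.569 to 8.044. In the cKO libraries it was 8.087 (replicate 2), 8.240 (replicate 1), 7.671 (replicate 3) and 8.750 (replicate 4). An uneven dissection was not tested as the cause.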

How the results depend on the processing

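The settings without WT replicates 2 and 5, with the meningeal or endothelial mean as a covariate and without Slc38a3 in the lists were chosen after seeing the data. Slc38a3 passed in every setting run, with log2 fold changes of -3.35 to -2.66. The 59 genes of cKO against WT became 216 without the sex term (51 of the 59 among them), 199 with DESeq2 (all 59 among them), 11 in females only, 3 in males only, 15 without WT replicates 2 and 5 and 13 with the meningeal covariate. With the endothelial covariate 40 genes passed, 27 of the 59 among them, and the median SE of the 59 was 0.0656. In each of these settings all 59 kept their direction, with a median of 95.8 to 103% of the change. Their median SE of 0.0558 grew to 0.0709 in females only, 0.0829 in males only, 0.0631 without WT replicates 2 and 5 and 0.0675 with the meningeal covariate, where the counts fell. The cause of the higher counts was not tested. With 1 library left out the count ranged from 10 (without cKO replicate 2) to 65 (without cKO replicate 4). In the same fits the lists numbered 13 to 20, the sex genes 9 to 16 and, in the 7 that could be made, the interaction genes 1. Without cKO replicate 2 or WT replicate 1, on which it rests, the interaction could not be fitted. The 18 lists became 0 with an estimated correlation and 4 with fry, and all 18 were called without Slc38a3 in them. The 9 sex genes became 24 and the 1 interaction gene 7 with DESeq2, and the interaction genes 919 without a filter, of which 875 had a mean under 10. In the single-sex fits 1 group holds 1 library, which is assumed to vary like the other group. The genotype estimates without cKO replicate 2 or WT replicate 1 rest on the same comparisons, of males only and of females only. camera has no robust option, so robust limma was not run for the lists. No scaling moved the median of all genes by 0.1 on the log2 scale. Genes with few reads limit the precision, since all libraries were of like depth.

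Of 958 comparisons of 41 named calls with an alternative, 719 kept the call, 239 lost it and 0 turned. With each of the 9 libraries left out, 3 of the 33 named genotype calls other than Slc38a3, 6 of 7 for sex and 7 of the 18 lists held, and Sorcs2 held with each of the 7 that could be left out. Of 3081 comparisons of named genes not called, 48 passed and 52 turned. Of 432 comparisons of called lists, 366 kept the call, 58 lost it and 8 turned.

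The log2 fold changes that turned, given for lists as the median where the test turned, were as follows, and the cause was not tested. Without the sex term these were Mag (-0.06541), Slc4a5 (-0.1907), mt-Nd1 (-0.03682), mt-Cytb (-0.04055) and the list of oligodendrocyte and myelin genes (-0.07788). The following are given as ranges over the libraries left out. Without WT replicate 1, and in females only at the same end of the range, they were Kcnj13 (-1.05 to 4.064), Prlr (-0.2908 to 0.7168), Col8a1 (-1.151 to 2.063), Slc4a5 (-2.044 to 4.393), Ccdc39 (-0.02882 to 0.2621), mt-Cytb (-0.09645 to 0.1193), Rora (-0.08445 to 0.3166), Cux2 (-0.06786 to 0.3696), Tac1 (-0.00674 to 0.4612), Penk (-0.05884 to 0.8882), Ftx (-0.05042 to 0.4431), the list of meningeal and fibroblast genes (0.06894 to 0.7497) and the list of immediate early genes (-0.2779 to 0.0503). Without cKO replicate 2, and in males only at the same end, they were Slc38a9 (-0.2518 to 0.025), Rarres2 (-0.08797 to 0.5164), Hba-a1 (-0.3524 to 0.06872), Ndufv1 (-0.03773 to 0.1954), mt-Nd5 (-0.1797 to 0.1542), Kdm5c (-0.2629 to 0.04302), Usp9x (-0.3198 to 0.03808), the list of GABA signalling (-0.01866) and the list of blood cell genes (-0.4551 to 0.06872), of which GABA signalling, given as its value, turned in males only. With the meningeal covariate they were Col8a1 (-0.22) and Slc4a5 (-0.7762), and with the endothelial one Prlr (-0.1998), Col8a1 (-0.2304), Slc4a5 (-0.9881), mt-Cytb (-0.06594) and Penk (-0.1522). With 1 further library left out, mt-Cytb was at -0.008022 (without WT replicate 2), -0.004435 (without WT replicate 3) and -0.009596 (without cKO replicate 3), and mt-Nd5 at 0.006826 (without WT replicate 4) and 0.008846 (without WT replicate 5).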

Other observations

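The tests of hypotheses in this part, and the genes named in it, were chosen after the results were seen. Of the 59 genes that changed between cKO and WT, 34 are in none of the fixed lists, 16 higher and 18 lower. Among those that rose were Abhd4 (1.23-fold, 1810.1 ± 91.5 in cKO and 1537 ± 50.7 in WT), the mitochondrial carrier gene Sfxn5 (1.18-fold) and Gas5, a host gene of small nucleolar RNAs (1.21-fold, 1908 ± 70.6 in cKO and 1615 ± 76.0 in WT). Among those that fell were the neurofilament gene Nefh (1.22-fold, 1757 ± 111 in cKO and 2213 ± 77.2 in WT), the semaphorin receptor gene Plxnd1 (1.22-fold), the mitochondrial glutamate carrier gene Slc25a18 (1.30-fold, 891 ± 72.5 in cKO and 1225 ± 84.3 in WT), Csrp1 (1.245-fold) and Far2 (1.23-fold). All of these lost their call without cKO replicate 2, WT replicate 1 or both.

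Scd1, Acaca and Acly, of fatty acid synthesis, fell beside the cholesterol genes. The hypothesis that fatty acid synthesis genes fell together was tested with a list of 20 genes, of which 3 fell, 0 rose and 15 had a fold change below 0 (median -0.09). camera with an estimated correlation gave p = 0.0136 over the whole list. The genes that passed had prompted the list. Over the 17 others camera with an estimated correlation gave p = 0.07144 (median -0.09). A fall of the group beyond the genes that prompted it stays open. Scd1 was at 3062 ± 347 in cKO and 5017 ± 456 in WT, Acly at 6018 ± 89.9 in cKO and 6922 ± 245 in WT and Fasn, which did not pass, at 16922 ± 353 in cKO and 17844 ± 678 in WT.

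A strain variant carried along with the edited Slc38a3 copy could change its neighbours. Of 162 genes within 5 Mb, 8.64% had an unadjusted p under 0.05, against 11.4% elsewhere (two-sided Fisher's exact test, p = 0.3199), and 0 passed limma's adjusted threshold. An excess near the gene was not detected, and changes in single neighbours stay open.

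Tbc1d1 and Tlr1, both on chromosome 5, differed between the sexes although neither is sex-linked. Tlr1 was at 81.8 ± 12.1 normalized counts in males (SD, n = 4) and 26.7 ± 4.81 in females (SD, n = 5). Between them lie 6 tested genes, of which 2 had an unadjusted p under 0.05 for sex, and C030018K13Rik and Gm57288 fell in cKO (2.04-fold and 1.84-fold). Sorcs2 lies on the same chromosome but far outside the stretch from Tbc1d1 to Tlr1 (64313647 to 65090906). It was low in the cKO males only and did not follow sex as those 2 genes did. In a principal component analysis of the log2 values, the first component held 25.6% and the second 17.6% of the variance. The first parted the sexes by a narrow gap, with the 5 females at 2.85 to 24.2 and the 4 males at -27.2 to -3.58. Since sex and genotype were unevenly split, it is not free of genotype. The cKO libraries lay at -27.2 to 2.85 and the WT libraries at -17.6 to 24.2. On the second component cKO replicates 1 and 4 lay apart, at 22.7 and 22.2, with the other libraries at -18.4 to 3.88.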
